A study of Mus musculus with 2 samples.

How the data were processed

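Total RNA was sequenced from the gastrocnemius, the large calf muscle, of 2 male B6Cast F1 mice aged 25 days, the first-generation cross of the C57BL/6J and CAST/EiJ strains. Each animal gave 1 library from 300 ng of RNA, per the labels. The labels name a profile of ERCC spike-ins (synthetic RNAs added in known amounts) for stranded libraries with ribosomal RNA reduced. They number the tissue samples as different males, so the libraries were treated as separate animals of 1 group, although both carry the same donor entry.

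The deposited tables hold, for each library, 1 gene table, 1 transcript table of the same kind and a second transcript table. Expected counts, which need not be whole, TPM and FPKM in the first pair of tables were computed by the authors, and their columns are those RSEM writes, per the file headers. TPM, the share of transcripts scaled to a fixed total, is corrected for transcript length, and the deposited effective lengths were 99 bases below the lengths. The first pair also gives, per the file headers, posterior mean TPM with the bounds of an interval whose level is not stated there, and the percent of a gene's abundance taken by each transcript. The second transcript table holds estimated counts and TPM in the columns kallisto writes, per the file headers. The accompanying descriptions deposited with the tables name mm10 and the GENCODE M21 annotation, and derive the first pair from a transcriptome alignment and the second table from 1 read file. Tool names, versions, the aligner and the use of strand in counting are not given in the sources used here. FPKM was not used. The first tables were made over 81881 gene entries, of which 55536 matched M21 genes by identifier, 96 were spike-ins and 26248 were named only by a number. The last kind held 1 count in each library and was left out, as was phiX with 0 counts. Deposited TPM is a share of all entries, so a few very abundant short RNAs lower the TPM of every other gene. Genes sharing reads with near-identical copies, pseudogenes and overlapping or antisense genes are uncertain.

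Expected counts summed to 35098487 in animal 1 and 37428588 in animal 2. A count of 0 allows up to 3 counts, or 0.0855 and 0.0802 CPM (counts scaled to the library total). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Levels are the deposited TPM, given per animal or as mean ± SD over the 2 animals. A gene was called detected at TPM of 1 or more in both libraries. Lower values are called not detected at this threshold, not absent. Transcripts of the second table were summed to genes. The posterior intervals were used only in choosing named genes, for the bound on Gm10095 and beside the TPM of mt-Co3 and Gm28437.

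Because the series has 1 group, no condition was compared, and no exact test over 2 animals can go below p = 0.5 (two-sided). The animals were compared as libraries. Expected counts were rounded to whole numbers and scaled by TMM (edgeR 4.0.16 in R 4.3.3). Genes with a summed count of 20 or more were tested by an exact conditional binomial test, two-sided, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a ratio over 2-fold, with a prior count of 0.5. This test compares these libraries, not conditions, and its error is sampling error alone. For gene lists, the median log2 ratio (animal 2 over animal 1) of members with mean TPM of 1 or more was placed among 10000 random lists of the same size, matched on 20 bins of mean expression. A list outside the central 95% was called apart. Lists with fewer than 3 such members were not tested. Random lists hold unrelated genes, whereas genes of 1 cell type vary together, so the range is narrower than that of co-expressed genes. The scaling left a median log2 ratio of 0.0039 over nuclear protein-coding genes at mean TPM of 5 or more, against 0.12 for the ratio of TPM. Single genes differ between these ratios by more or less than that.

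Tested on simulated data with the real library sizes and 14755 genes, the binomial test called 99 of 100 genes changed 3-fold, 100 of 100 changed 4-fold and 0 of 14555 unchanged genes. The changed genes were drawn from those with a summed count of 100 or more. The simulated counts varied by sampling alone and the real libraries differed by more, so this gives no rate of false calls for the real libraries. The list step placed 20 of 20 lists shifted by 0.5 log2 and 4 of 100 unshifted lists outside the range. Its simulated genes varied independently, so it does not give the rate for genes that vary together.

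The 37 gene lists (417 symbols, of which 416 matched), the gene pairs, the isoform genes and the alternatives were fixed before the data were examined. So was the rule for named genes. It takes the 10 most abundant nuclear protein-coding genes, the 5 most abundant mitochondrial ones, all sarcomeric myosin heavy chains, the pair members, up to 4 top members per list (only the top member where the list's median is under 1 TPM) and the sex-linked genes. It adds the 10 largest differences each way between the animals among nuclear genes at mean TPM of 5 or more with separate intervals, the 5 largest gaps each way between the quantifications at mean TPM of 10 or more, and 10 isoform genes. Some genes the rule takes are not reported here. Genes outside the rule are marked as chosen after their values were seen. Alternatives varied the detection threshold, the quantification, the unit, the TPM denominator, the pseudocount, the scaling (DESeq2 1.42.0 size factors, spike-ins, none), the count filter, the fold, the test, the random lists and the animals included. Those added after the data were seen are named as such. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.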

Results

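Gene expression was measured by total RNA-seq in the gastrocnemius of 2 male B6Cast F1 mice at 25 days of age, with 1 library per animal and 35098487 and 37428588 expected counts. The labels give 1 group, so the data describe the transcriptome of this muscle at this age and the spread between the animals. Values are TPM, given as mean ± SD over the 2 animals unless an animal is named. Coordinates are those of mm10.

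At TPM of 1 or more, 10792 of 55536 annotated genes were detected in both animals, and 9950 of these were protein-coding. A further 327 genes passed in animal 1 alone and 496 in animal 2 alone. The most abundant nuclear messenger RNAs were those of the contractile apparatus and of energy supply in fast fibres. Skeletal actin, Acta1 (chromosome 8, 123891769 to 123894751), stood at 22842 ± 1262 TPM (SD, n = 2). It was followed by the fast regulatory light chain Mylpf at 18849 ± 503 and the muscle creatine kinase Ckm at 16973 ± 586. Fast troponin T, Tnnt3, reached 12923 ± 961, the light chain Myl1 11184 ± 464, tropomyosin Tpm1 10102 ± 107 and the heavy chain Myh4 9905 ± 625. The calcium pump Atp2a1 (9309 ± 725), the glycolytic enzyme Aldoa (8580 ± 497) and fast troponin C, Tnnc2 (7495 ± 1354), completed the first 10. These 10 genes held 33.0% of nuclear protein-coding TPM in animal 1 and 31.5% in animal 2, and the first 100 held 55.7% and 54.2%.

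Mitochondrially encoded genes took 24.1% of all TPM in animal 1 and 18.3% in animal 2, or 21.2% ± 4.09 (SD, n = 2). In expected counts these shares were 21.7% (Wilson 95% interval 21.67 to 21.70) and 17.2% (17.22 to 17.25). Most of this came from the ribosomal RNAs mt-Rnr2 (83907 ± 8503 TPM) and mt-Rnr1 (75073 TPM in animal 1, 44316 in animal 2). Together they took 16.5% and 12.2% of all TPM in animals 1 and 2. How far the reduction of ribosomal RNA acted on them in each library was not measured. The mitochondrial messenger RNAs took 7.61% and 6.10%, but 8.73% and 8.96% in the second quantification. In the first quantification the most abundant mitochondrial messenger RNAs were mt-Co1 (14310 ± 1075 TPM), mt-Cytb (8510 ± 607), mt-Nd1 (6269 ± 12.5), mt-Atp8 (6123 ± 2513) and mt-Co3 (5776 ± 5726). The order differed in the second, where mt-Atp6, chosen after its values were seen, had 19970 TPM against 5384 in the first, and mt-Atp8 had 0. The SD of mt-Co3 was almost as large as its mean, because the first quantification gave 9825 TPM in animal 1 and 1727 in animal 2, while the second gave 3989 and 4161. Rn7s1 and Rn7s2, the RNA of the signal recognition particle, together held 26.6% of all TPM in animal 1 and 29.8% in animal 2 in the first quantification, and 4.39% and 4.89% of counts.

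Heavy chain genes of fast fibres took most of the myosin transcripts. Myh4, the heavy chain of IIB fibres (chromosome 11, 67238029 to 67260446), made up 78.7% ± 1.52 (SD, n = 2) of the summed TPM of the 10 sarcomeric heavy chain genes. Myh1, of IIX fibres, made up 11.6% ± 1.42, Myh2, of IIA fibres, 5.60% ± 0.919, and Myh7, of slow fibres (chromosome 14, 54970684 to 54994626), 2.51% ± 1.04. The perinatal chain Myh8 held 0.914% ± 0.145, and the cardiac alpha chain Myh6 0.546% ± 0.135. The embryonic chain Myh3, Myh7b and Myh13 held 0.0512%, 0.0146% and 0.0144%. Myh15 had 1 count in animal 1 and 0 in animal 2. The order of the first 4 genes was the same in both animals. These genes are close paralogs, and the second quantification set Myh4 at 73.3%, Myh1 at 18.7% and Myh6 at 0.178%.

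**Figure D1:**
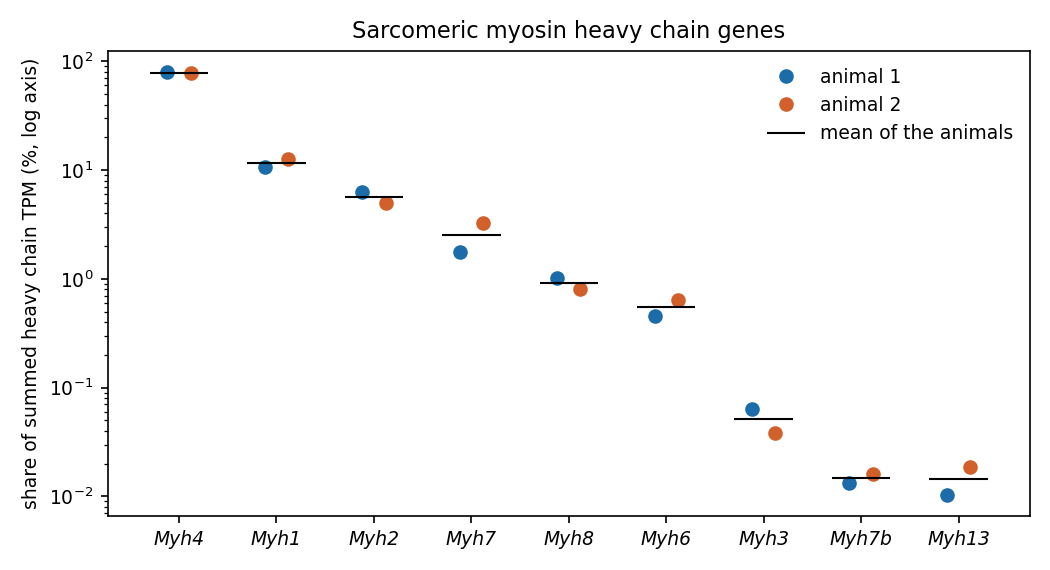
Share of each sarcomeric myosin heavy chain gene in the summed heavy chain TPM (percent, log axis) in animal 1 (blue) and animal 2 (orange), with the mean as a line. Myh4 sits near 78.7% and Myh7 near 2.51%, and Myh15 is not drawn because it was at 0 in animal 2.

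All 11 fixed pairs of fast and slow genes had the fast member higher in both animals. The mean log2 ratio ran from 1.67 for Mybpc2 over Mybpc1 (1746 and 549 TPM) to 6.29 for Tnni2 over Tnni1 (7433 and 102 TPM), the inhibitory troponins. Myh4 over Myh7 stood at 5.04 ± 0.645 (SD, n = 2), Mylpf over Myl2 at 5.70 ± 0.676, Tnnt3 over Tnnt1 at 5.79 ± 0.627 and Atp2a1 over Atp2a2 at 5.87 ± 0.765. Myl1 over Myl3, Tnnc2 over Tnnc1 and Tpm1 over Tpm3 lay between 5.41 and 5.53. Casq1 over Casq2, the calcium stores of the reticulum, stood at 6.28 ± 0.182, and Myoz1 over Myoz2 at 2.68 ± 0.171. In 10 of the 11 pairs the ratio was lower in animal 2 than in animal 1, with Mybpc2 over Mybpc1 the exception (1.66 and 1.67). The median over pairs was 6.08 in animal 1 and 5.18 in animal 2.

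All 6 pairs of adult and developmental genes had the adult member higher in both animals, and the developmental members still differed widely in level. Cardiac actin, Actc1, remained at 877 ± 19.9 TPM (SD, n = 2), a log2 distance of 4.70 ± 0.112 from Acta1. Myh4 exceeded Myh8 (115 ± 23.3 TPM) by 6.44 ± 0.202 and Myh3 (6.49 ± 2.59 TPM) by 10.63 ± 0.50. The troponin Tnnt2 (2.35 ± 0.0919 TPM) and the light chain Myl4 (2.86 ± 0.955 TPM) lay 12.43 and 11.98 below their adult partners. The adult acetylcholine receptor subunit Chrne stood at 9.28 ± 0.516 TPM, and the fetal subunit Chrng, with 5 counts in each library, was not detected at this threshold. The imprinted list had a median of 5.25 ± 0.693, and its highest members were the noncoding H19 at 1039 ± 57.9 TPM, the growth factor Igf2 at 97.4 ± 0.969, Cdkn1c at 39.2 ± 2.52 and Grb10 at 30.2 ± 0.912.

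**Figure D2:**
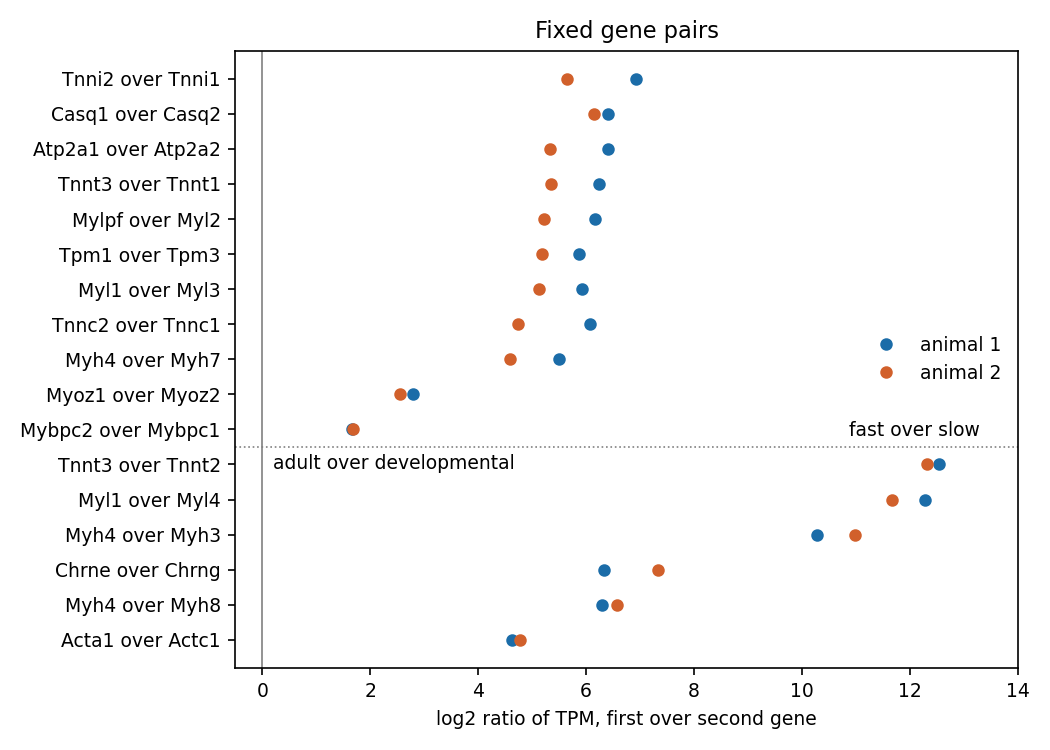
Log2 ratio of TPM between the genes of each fixed pair in animal 1 (blue) and animal 2 (orange); the dotted line separates the 11 fast over slow pairs from the 6 adult over developmental pairs. All ratios are above 0, and 10 of the 11 fast over slow ratios are lower in animal 2.

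Genes of glycolysis and of the common sarcomere had higher median levels than the nuclear genes of oxidative phosphorylation and of fatty acid oxidation. The median member of the glycogen and glycolysis list stood at 649 ± 33.1 TPM (SD, n = 2), with Gapdh at 3970, Eno3 at 2891 and the phosphorylase Pygm at 2564. The excitation and calcium list had a median of 159 ± 9.12, with Atp2a1 highest, followed by the calcium buffer Pvalb at 7349, Casq1 at 2118 and the release channel Ryr1 at 659. Common sarcomere genes had a median of 570 ± 60.2, including Tpm2 at 3449 and the giant proteins Ttn at 2609 and Neb at 2161. In the phosphagen and purine list, Ak1 stood at 793, Ckmt2 at 536 and Ampd1 at 452. Nuclear oxidative phosphorylation genes had a median of 370 ± 34.4, led by Atp5b at 1520, Cox8b at 762, Cox4i1 at 682 and Cox6a2 at 610. Fatty acid oxidation genes had a median of 105 ± 13.5, with the oxygen store myoglobin, Mb, at 1188 ± 271 and Fabp3 at 361. Heat shock genes were led by Hspb6 at 448, Hspa8 at 423 and Cryab at 397. Cytosolic ribosomal protein genes had a median of 171 ± 0.796, with Rps14 at 294.

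Regulators were lower. Among myogenic regulators Mef2c stood at 132 ± 4.18 TPM (SD, n = 2), Mef2d at 61.4, Myf6 at 43.9 and Srf at 30.5. The synaptic genes Chrnb1, Musk, Ache and Rapsn lay at 13.5, 10, 9.89 and 9.45. Satellite cell genes, of the muscle stem cell, had a median of 1.01 ± 0.0141, with Sdc4 at 24.4, Cdh15 at 5.71 and Chodl at 4.37. Cell cycle genes had a median of 0.633 ± 0.0389, and of the 10 only Pcna, at 7.02, passed the threshold in both animals. Clock genes had a median of 6.43 ± 0.665, led by Tef at 44.1 and Nr1d1 at 39.9. Immediate early genes were led by Nr4a1 at 23.7, Jun at 22.3 and Dusp1 at 18.1. Nuclear noncoding RNAs were led by Malat1 at 1054 and Neat1 at 145. The Y-linked genes Ddx3y (20.5 TPM), Eif2s3y (15.8), Uty (5.0) and Kdm5d (3.35) were detected in both animals, and Xist, with 6 and 3 counts, was not. The labels give both animals as male.

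Among the marker lists of cells other than the muscle fibre, those of connective tissue, blood and vessels had the highest medians. These are levels in bulk tissue, not cell fractions, and they cannot show whether a member's RNA came from those cells or from the fibre itself. The fibroblast and fibro-adipogenic list had a median of 27.7 ± 2.78 TPM (SD, n = 2), with the collagens Col1a1 at 667 ± 279, Col1a2 at 412 ± 135 and Col3a1 at 229 ± 0.346. Erythroid genes were led by the globins Hbb-bs at 207, Hba-a1 at 177 and Hba-a2 at 152, near-identical copies whose reads are hard to assign. Tendon genes had a median of 9.29 ± 1.64, led by Fmod at 54.5 and Thbs4 at 47.3. Endothelial genes had a median of 6.38 ± 1.14, led by Fabp4 at 65.6 and Egfl7 at 17.2. Mural cell genes had one of 5.61 ± 0.346, led by Rgs5 at 57.7 and Abcc9 at 48.4. Macrophage genes had one of 4.28 ± 0.127, led by Lyz2 at 13.5 and C1qb at 5.54. Schwann cell genes, of the myelinating glia of nerve, had one of 1.39 ± 0.601, with Pmp22 at 26.0 and Mbp at 19.4. The adipocyte list had a median of 1.19 TPM in animal 1 and 0.595 in animal 2 (mean 0.89, and 1.53 in the second quantification). Medians were under 1 TPM for the brown fat, neuron, neutrophil and lymphocyte, epidermis, bone and cartilage, and cardiac lists. The top members of these lists were Cfd (6.53), Ppara (7.41), Prph (0.495), Retnlg (0.10), Krt10 (1.99), Col2a1 (3.18) and Myh6 (68.3; 30.4 in the second quantification).

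**Figure D3:**
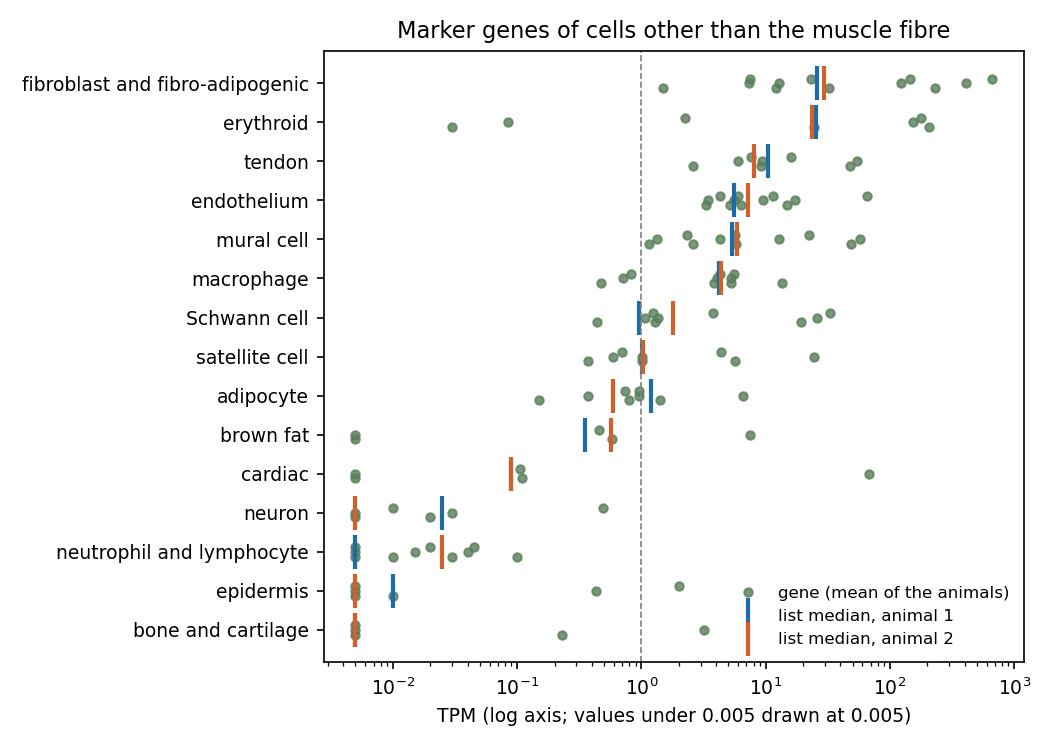
TPM (log axis, values under 0.005 drawn at 0.005) of the marker genes of cells other than the muscle fibre, 1 green point per gene (mean of the animals), with each list's median in animal 1 (blue) and animal 2 (orange); the dashed line marks 1 TPM. The fibroblast and fibro-adipogenic list has the highest median, 27.7 TPM, and the bone and cartilage list the lowest, 0 TPM.

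Dominant isoforms were read for 28 genes whose splicing changes during muscle development. For 20 of them both animals and both quantifications named the same transcript. In the first quantification Tpm1-205 took 97.6% ± 0.0913 (SD, n = 2) of Tpm1, Ryr1-202 94.6% ± 0.0527 of Ryr1, Atp2a1-201 94.3% ± 7.73 of Atp2a1 and Ldb3-207 78.8% ± 0.232 of Ldb3. Tpm2-202 took 43.7% ± 0.229 of Tpm2. The second quantification gave mean shares of 76.3% for Tpm1-205, 93.0% for Ryr1-202, 99.8% for Atp2a1-201, 75.0% for Ldb3-207 and 51.7% for Tpm2-202. The SD between animals does not cover this gap between quantifications. The quantifications disagreed on Tnnt3 (Tnnt3-201 at 42.1% against Tnnt3-225 at 52.3%), Myl1 (Myl1-202 at 68.8% against Myl1-207 at 38.5%) and Ttn (Ttn-215 at 28.7% against Ttn-205 at 27.3%). For Neb the first quantification named different transcripts in the animals, and for Pkm the second did.

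The animals were similar across genes, with differences above binomial counting error at high levels. Pearson's r of log2(TPM + 1) across 55536 genes was 0.993 and Spearman's rho 0.924, where genes are not independent replicates. Nuclear protein-coding genes at 100 TPM or more had a median absolute log2 ratio of 0.071, against 0.014 from binomial sampling alone. At 1 to 5 TPM these values were 0.15 and 0.10. Chi-square per degree of freedom over 12805 nuclear protein-coding genes was 17.7, a mean over genes, and the median chi-square per gene was 1.25. Spike-ins took 0.543% and 0.573% of counts (Wilson 95% intervals 0.540 to 0.545 and 0.571 to 0.576), and the log2 ratio of gene counts per spike-in count, animal 2 over animal 1, was -0.078.

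Between these libraries, 256 of 14754 genes tested were called, 111 higher in animal 2 and 145 higher in animal 1. With the ratio of TPM in place of scaled counts the split was 137 to 103. Among protein-coding genes at mean TPM of 5 or more, 30 of 5980 were called, 7 higher in animal 2 and 23 higher in animal 1. Of 608 pseudogenes 59 were called. Among the 10 largest differences with animal 2 higher, the protein-coding genes included Dusp10, a phosphatase of stress kinases (4.35 and 12.7 TPM in animals 1 and 2, log2 ratio 1.43), and Cish, an inhibitor of cytokine signalling (8.91 and 39.2 TPM, 1.37). Log2 ratios of named genes are of scaled counts, and the ratio of TPM gave 2.14 for Cish. Gm10273, also protein-coding by annotation, had 1.72, but -7.63 in the second quantification. The pseudogene Gm28437 (chromosome 1, 24613189 to 24613971) had 2.11, and Gm10359 (1.61), Gm11826 (1.11) and the snRNA Gm24305 (1.21) followed. Gm10095, with 0 counts in animal 1, was at least 120-fold higher in animal 2 by counting error alone, taking 3 counts as the floor. The deposited intervals, up to 3.15 TPM in animal 1 and from 23.6 TPM in animal 2, allow a much smaller ratio. Protein-coding genes named here, other than Gm10273, were over 2-fold apart the same way in the second quantification.

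Lower in animal 2 were Angptl7 (26.7 and 8.89 TPM, log2 ratio -1.70), the metal-binding Mt2 (69.9 and 24.1 TPM, -1.67), Arrdc2 (19.2 and 8.47 TPM, -1.66), the clock gene Per1 (18.2 and 8.22 TPM, -1.44), Id1, an inhibitor of differentiation (8.97 and 3.78 TPM, -1.37), 1500015O10Rik (8.38 and 3.55 TPM, -1.35) and the deubiquitinase Otud1 (15.5 and 6.86 TPM, -1.29). Gm4332 (-1.79), Gm7336 (-1.37) and the snoRNA Gm25291 (-1.45) completed the 10. By the ratio of TPM, Arrdc2 had -1.18 and Per1 -1.145. None of the pseudogenes and small RNAs named here was over 2-fold apart in the second quantification, where Gm28437, Gm11826 and Gm7336 had log2 ratios of 0.15, 0.60 and -0.38 and the others were at or near 0 TPM. Each named gene passed the exact binomial test with an adjusted p of 8.2e-04 or less, which compares these libraries only.

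By gene list, 16 of the 28 lists tested lay outside the central 95% of matched random lists, where 1.4 would for lists of unrelated genes. Genes of 1 list can vary together and some lists share genes, so 1.4 is not the number expected for them. Of the 16 lists, 5 were higher in animal 2 and 11 lower. The largest shifts upward were in Schwann cell and slow sarcomere genes. All 8 Schwann cell genes in the comparison had a higher ratio in animal 2, with a median log2 ratio of 0.96 (random lists -0.17 to 0.18), and 3 were called over 2-fold, including Mal (1.19) and Ncmap (1.21), which were chosen after their values were seen. By adjusted p alone, 7 of 9 counted members were higher, or 8 adjusted over the list alone. Pmp22 and Mbp had 0.79 each. All 10 slow sarcomere genes had a higher ratio, with a median of 0.73 (random lists -0.12 to 0.07). None exceeded 2-fold, and 9 passed the adjusted p, also 9 adjusted over the list alone. Myl2, Myh7, Myl3 and Tnni1 had 0.80, 0.70, 0.76 and 1.00, and Tpm3, the slow tropomyosin outside the list, 0.56. Mybpc1 had -0.18, and Myh2 had 811 TPM in animal 1 and 604 in animal 2. Fast sarcomere genes had a median of -0.13 (random lists -0.12 to 0.06), with 10 of 11 lower past the adjusted p, and -0.01 by the ratio of TPM, where random lists shift too and the list stayed outside. Mural cell (0.30), neuromuscular junction (0.15) and fatty acid oxidation (0.08) genes also lay above their ranges, by less.

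The largest downward shift was in atrophy and glucocorticoid response genes, with a median of -0.73 (random lists -0.09 to 0.07). Of 15 members 14 had a lower ratio, 13 passed the adjusted p (13 adjusted over the list alone) and 4 were called over 2-fold, Mt2 and, chosen after their values were seen, Mt1 (-1.09), Foxo1 (-1.14) and Ddit4 (-1.03). The ubiquitin ligase Trim63 had -0.62, the glucocorticoid-induced Tsc22d3 -0.82, Mt2 -1.67 and Pdk4, a regulator of glucose oxidation, -0.23. The kinase Sgk1 had 0.23. Tendon genes followed with a median of -0.45 (random lists -0.13 to 0.12), 6 of 8 lower past the adjusted p and 6 adjusted over the list alone. Fmod had -0.81 and Thbs4 -0.34. Fibroblast and fibro-adipogenic genes had -0.20, with Col1a1 (864 and 469 TPM) at -1.01, called over 2-fold, and Col3a1 (229 TPM in both) at -0.18. Mitochondrially encoded genes had -0.26, with 12 of 13 lower. Among the 12 was mt-Co3, with -2.63 in the first quantification and -0.089 in the second. Imprinted (-0.26), nuclear noncoding (-0.31), sex-linked (-0.27), macrophage (-0.24), erythroid (-0.24) and immediate early (-0.22) genes lay below their ranges. With the mean in place of the median, 7 of the 16 lists stayed outside: slow sarcomere, mural cell, Schwann cell, mitochondrially encoded, glucocorticoid, fibroblast and tendon. At mean TPM of 5 or more the neuromuscular junction, mural cell, sex-linked and macrophage lists were inside, and with random lists not matched on expression the fatty acid oxidation and nuclear noncoding lists were. Without a TPM filter, the fatty acid oxidation, nuclear noncoding, sex-linked and macrophage lists were inside. By the ratio of TPM, an alternative chosen after seeing the data, the nuclear noncoding list was inside and the macrophage list had 0.13. The other 12 tested lists lay within their ranges, with medians from -0.08 (myogenic regulators) to 0.08 (endothelium). They were the common sarcomere, developmental, excitation, glycolysis, phosphagen, oxidative phosphorylation, myogenic, satellite cell, clock, heat shock, ribosomal protein and endothelial lists. In the second quantification the developmental (-0.14), clock (-0.15) and oxidative phosphorylation (0.04) lists lay outside. Each animal is 1 library, so no list has a test across animals.

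**Figure D4:**
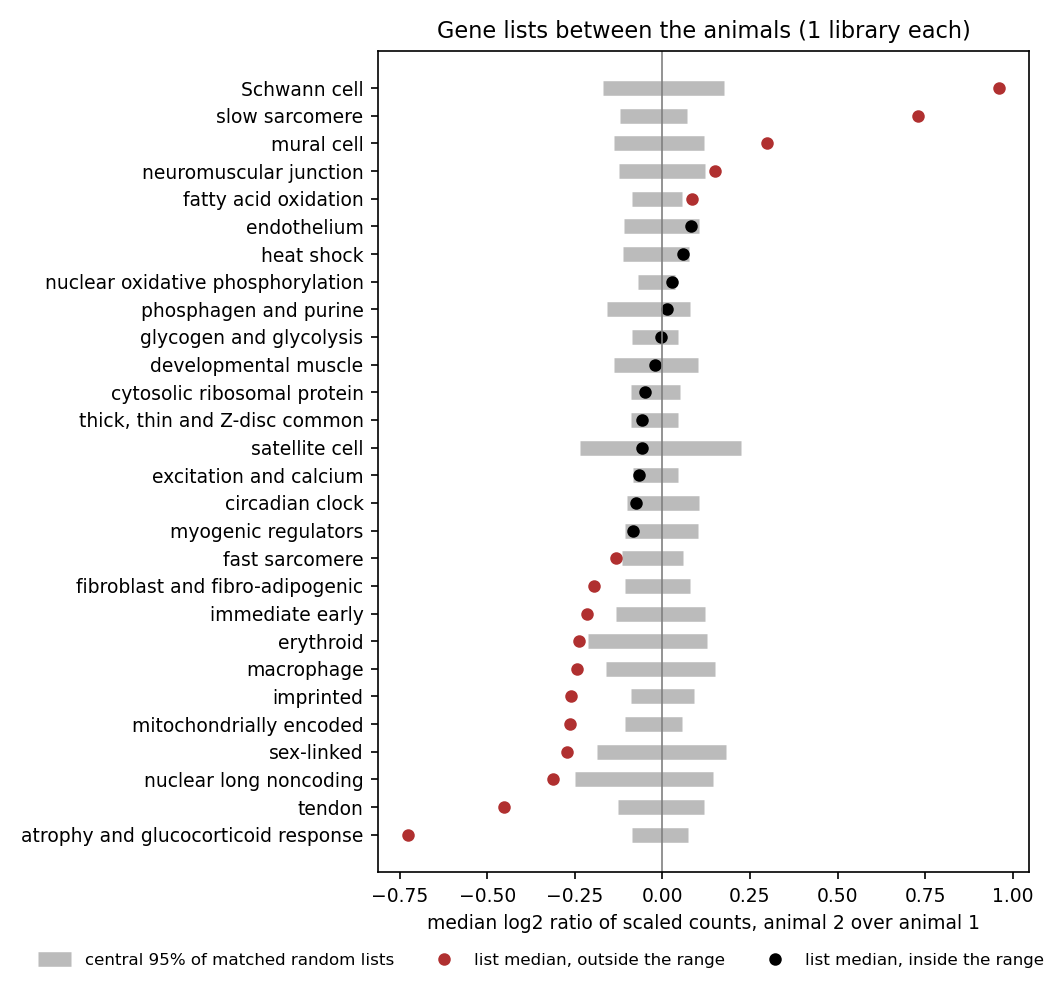
Median log2 ratio of scaled counts, animal 2 over animal 1, for the 28 gene lists tested; grey bars give the central 95% of 10000 matched random lists, red points lie outside and black points inside. Schwann cell (0.96) and slow sarcomere (0.73) genes lie farthest above their ranges, and atrophy and glucocorticoid response genes (-0.73) farthest below.

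The quantifications of the same library differed for some genes by more than the animals did. Pearson's r across genes between them was 0.949 in animal 1 and 0.950 in animal 2. Nuclear protein-coding genes were 1.41-fold (animal 1) and 1.44-fold (animal 2) higher in the second quantification at the median, where Rn7s1 and Rn7s2 took almost no TPM. Of 12963 genes considered, 1492 (11.5%) lay more than 2-fold apart in the same direction in both animals, 1025 higher and 467 lower in the second. The median shift was not removed from these counts, and among protein-coding genes 615 were higher and 57 lower. Of 216 small noncoding genes 160 were lower in the second, and of 671 pseudogenes 168 were higher and 227 lower. The genes most above in the second were Gm47283, Gm42420, Usp50, Gm47673 and Gm14506, with 28.5, 20.9, 18.4, 15.5 and 12.9 TPM against 0.030 or less in the first. Those most below were Rn7s1 and Rn7s2 (each 140852 TPM against 0.426), Rn7sk (14069 against 0), mt-Atp8 (6123 against 0) and Gm23472 (1838 against 0).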

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

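Of the 249 list values under alternatives, 223 kept their call, 20 lost the call, 5 gained one and 1 reversed. Direction was checked only for lists outside the range in the main comparison. DESeq2 and spike-in scaling shift all genes alike, so they could not change a call. All 11 fast over slow and all 6 adult over developmental pairs kept their direction under each alternative run, and r between the animals stayed between 0.987 and 0.994. Detected genes moved most with the threshold (6111 at 5 TPM). The second quantification set the mitochondrial share at 29.7%, Myh4 at 73.3% of heavy chain TPM and gene counts per spike-in count at -0.10 (log2). In the first, mitochondrial TPM equalled 53.6% of nuclear protein-coding TPM, which is a ratio to those genes and not a share of all TPM. Without either animal the mitochondrial share of all TPM was 18.3 to 24.1%, Myh4 took 77.7 to 79.8%, detected genes numbered 11119 to 11288, and for agreement between the quantifiers, genes over 2-fold apart numbered 1799 to 1997. The genes that differ between the animals numbered 256, and became 119 with a summed count of 100, 526 at 1.5-fold, 2078 with no fold threshold, 167 and 59 with edgeR's exact test at an assumed coefficient of variation of 0.1 and 0.2, and 166 among nuclear protein-coding genes, a set chosen after seeing the data. Fewer genes are tested in the first and last of these, and the second quantification shared 112 of its 216 calls with the 256. Lists outside the range fell from 16 to 7 with the mean, and the cause was not tested. The macrophage list reversed to 0.13 for the ratio of TPM, chosen after seeing the data, and Gm10273 to -7.63 in the second quantification; the cause was not tested. Genes over 2-fold apart between quantifications numbered 861 at 5 TPM, 4279 at 1.5-fold, 773 at 4-fold and 672 among protein-coding genes. These counts include the median shift of nuclear protein-coding genes, 1.41-fold in animal 1 and 1.44-fold in animal 2. That shift lies close to the 1.5-fold threshold, so the count there is not a measure of gene-level disagreement. At 100 TPM or more the animals differed by more than binomial sampling gives (0.071 against 0.014, median absolute log2 ratio). At 1 to 5 TPM they did so too (0.15 against 0.10), so these values do not show where depth limits. Genes near 3 counts, such as Chrng and Xist, are not resolved.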

Other observations

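Of the tests below, those of scaling, of fast fibre share, of the clock, of the summed count and of the second quantification were chosen only after the result was seen. No biological explanation was tested against the design, since the labels give 1 group, and every explanation is a hypothesis found on the same 2 libraries.

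The adipocyte genes had too few members at 1 TPM for the list comparison, but 3 of 7 counted members were lower in animal 2 past the adjusted p, and 5 adjusted over the list alone. They were Adipoq at 2.07 and 0.74 TPM, Pck1 at 1.01 and 0.48 TPM and Cfd at 8.16 and 4.90 TPM. These genes were chosen after their values were seen, apart from Cfd. Atp5a1, the alpha subunit of ATP synthase, also chosen after its values were seen (chromosome 18, 77773729 to 77782869), was 2.09-fold higher in animal 2 (358 and 810 TPM) and was the only gene of the 28 in the oxidative phosphorylation list called over 2-fold, with 524 and 1243 TPM in the second quantification.

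Slow sarcomere and Schwann cell genes were higher in animal 2. The smallest medians over 9 other settings were 0.61 and 0.79, outside the random range in all 9, the second quantification among them. A change of scaling factor moves the random lists alike, so those settings could not change the call. Depth was not varied, so its part was not tested. If a lower share of fast fibres raised all other cell types alike, the tendon and fibroblast lists would be higher, and they stood at -0.45 and -0.20. The mural cell list stood at 0.30, and the amount of tendon in each piece is not known. The comparison therefore cannot decide on the share of fast fibres. More slow fibres in the piece and a change within slow fibres cannot be told apart. A set of 5 slow fibre genes in no list (Csrp3, Ankrd2, Pln, Myl6b, Ldhb) had a median of 0.066, inside the random range of -0.23 to 0.16. That is the value of Pln at 0.55 TPM, and without Pln the median was 0.14, against 0.73 for the slow sarcomere list. The other members ran from -0.33 to 0.42, with 2 higher and 1 lower past the adjusted p. More nerve stays open for the Schwann cell genes, since 8 others (Cldn19, Drp2, Gjc3, Pllp, Fa2h, Dhh, Cnp, Mag) had a median of 0.77 at percentile 99.98, with 4 higher and 0 lower past the adjusted p, although 5 lay under 1 TPM, so a longer stretch of nerve in the dissected piece may contribute to that part.

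Atrophy and glucocorticoid response genes were lower in animal 2. The median nearest 0 over 9 other settings was -0.61, outside the range in all 9, the second quantification among them. Here too a change of scaling factor could not change the call, and depth was not varied. A lower glucocorticoid or fasting signal stays open: 8 targets in no list (Klf9, Cebpd, Pik3r1, Lpin1, Errfi1, Rasd1, Nfkbia, Sesn1) had a median of -0.30, below the random range of -0.15 to 0.13, with 6 lower and 0 higher past the adjusted p. Another hour of collection also stays open. The 13 clock genes without Per1 and Per2 had a median absolute log2 ratio of 0.27, above the random range of 0.05 to 0.21. That measure drops direction: 6 of these genes were higher and 7 lower in animal 2, 3 and 5 of them past the adjusted p. It therefore cannot tell a shifted clock from scatter among these genes. The labels used here give neither feeding nor hour, so a lower glucocorticoid or fasting signal and another hour may both contribute.

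The mitochondrial gene mt-Co3 had 9825 TPM in animal 1 and 1727 in animal 2, and Gm28437, an unprocessed pseudogene on chromosome 1, had 2544 and 11887. The deposited intervals for mt-Co3 were 6270 to 7617 TPM in animal 1 and 4361 to 5632 in animal 2. For Gm28437 they were 4474 to 5824 and 7691 to 8967. Each TPM value lay outside its interval, and the intervals of the animals lay closer together than the TPM values. A real difference of mt-Co3 is argued against by the second quantification, with a log2 ratio of -0.089. A different split of shared reads may account for it, since 99.9% of the 31-base words of mt-Co3 were in the Gm28437 transcript. The summed counts had a log2 ratio of 0.018, which carries less weight: it lay above 11 of the other 12 mitochondrial messenger RNAs (-0.98 for mt-Atp8 to -0.12 for mt-Nd1) and below mt-Co1 alone (0.034).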
